A study of Mus musculus with 34 samples.

How the data were processed

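Dendritic cells were sorted by FACS from mouse spleen, and their RNA was extracted, amplified and biotin-labelled for arrays, per the labels' protocols. The deposited table holds 41155 probe sets on 34 arrays, and all its array columns were used. The deposited values are on a log2 scale (0.57 to 13.19) and were normalized by the authors, RMA and Partek 6.6 being named in the submitters' processing notes. Beyond the 5th decimal, 99.1% to 99.6% of probe sets share their digits among the arrays of an experiment label and 0.01% do so across labels, so the values carry an additive constant per probe set and label. Levels are therefore comparable within an experiment label only.

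Of the probe sets, 25335 have a gene in the annotation, 23521 of them exactly 1 gene symbol, and only these entered the tests. A gene with several probe sets (1082 genes) was represented by the one with the highest mean over all arrays, which gave 22180 genes. The 1814 probe sets shared by several genes and the 15820 without a gene name were tested apart. Stk3 has no probe set in the annotation, and the probe sets of Rag1, Clec9a and Cd74 are shared with other genes, so these are not analysed here.

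Groups were taken from the labels. Group-means models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 16 sorted-subset arrays shared a fit for the genotype effect in each subset, for the difference of these effects and for the WT subsets. The total DC comparison used its 7 arrays and the experiment 1 comparison its 7. The comparisons of experiment 2, each against a lone array, pooled the spread over the 11 arrays of experiments 1 and 2 and assume that the lone array varies like the others.

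Gene lists were written before the data were examined, as were the comparisons, the models that test them, most alternatives and the naming rule. Some tests of explanations and some added settings were chosen after the results were seen, as said where they are given. The 31 lists hold 598 entries, 547 of them measured. They cover CD8+ DC identity, CD8- DC identity, plasmacytoid DC, T cell, B cell, NK cell, macrophage and monocyte, neutrophil and granule, and erythroid markers, YAP/TAZ target genes, Hippo pathway components, oxidative phosphorylation, TCA cycle and pyruvate dehydrogenase, glycolysis, mitochondrial dynamics and biogenesis, cholesterol biosynthesis, ribosome biogenesis, MHC class I presentation and cross-presentation, MHC class II presentation, DC maturation and co-stimulation, interferon-stimulated genes, the non-canonical NF-kB pathway, canonical NF-kB targets, proliferation, BCL2 family and apoptosis, immediate-early and heat-shock genes, the p38 MAPK pathway, lysosome, the unfolded protein response, integrins and migration receptors, and sex-linked genes. The 29 lists with at least 5 measured members, sex-linked genes apart, were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Erythroid markers had 4 measured members, with mean signals per group from 3.70 to 4.32, and were not tested. The sex-linked genes were described and not tested as a list: Xist lay at 6.71 to 7.13, Eif2s3y at 4.06 to 6.15, Kdm5d at 3.75 to 5.41 and Uty at 4.19 to 5.02 over the arrays. Their mean moved with genotype in the sorted cells, 5.22 (4.93 to 5.45) in Mst1/2-KO against 5.68 (5.58 to 5.73) in WT CD8- DCs and 5.23 (4.87 to 5.55) against 5.53 (5.44 to 5.73) in CD8+ DCs. In total DCs it was 5.39 against 5.44. This mean joins Xist, which female cells express, with Y-linked genes, so it is not a direct measure of sex. Xist varied little over the arrays (6.71 to 7.13), so most of the fall in the sorted cells lay in the Y-linked genes. A difference in the sex of the animals between the genotypes therefore stays open there. Sex was not adjusted for, and whether it differed between the genotypes was not tested.

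The naming rule took the target genes, then, among called genes whose groups did not overlap, the 10 largest rises and 10 largest falls (5 each way and no overlap condition for the difference between subsets), up to 4 called members of each list with the largest change, and, where a list had fewer than 2, its 2 members with the smallest p. A comparison with 0 called genes took the 5 smallest p, and the lone-array comparisons took the 5 largest changes each way and up to 4 members per list. Predicted genes and clone names were skipped.

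The replicate numbers pair arrays only where arrays of 1 number share deviations from their group means. The correlation of these deviations was 0.19 to 0.42 between WT CD8+ and CD8- arrays, 0.16 to 0.28 between Mst1/2-KO CD8+ and CD8- arrays and 0.14 to 0.23 in experiment 1, each array correlating best with its own number, and it was -0.08 to 0.10 (CD8+), -0.03 to 0.10 (CD8-) and 0.06 to 0.18 (total) between genotypes, where the numbers do not pair the arrays. Within groups, arrays correlated at 0.986 to 0.996 across genes, which are not independent replicates.

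The fits were tested on simulated data with 22180 genes, of which 100 changed by 0.5 and 100 by 1 on the log2 scale. The shares recovered were 57% and 95% for CD8+ DCs, 62% and 95% for CD8- DCs, 27% and 89% for the difference of the effects, 69% and 98% for the WT subsets, 22% and 79% for total DCs, 54% and 80% for experiment 1, 22% and 67% for anti-CD40 and 13% and 59% for Rag1-KO against WT. In these runs 2 to 10 unchanged genes were called and 0 genes had the wrong direction. A maturation list shifted by -0.3 was called in every comparison except anti-CD40. The simulated values varied independently between genes and between arrays. These runs therefore do not show how the tests, above all the list test, behave where genes vary together.

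The alternatives were quantile and cyclic loess normalization, genes above the median gene only, the mean of all probe sets of a gene, an intensity trend with robust eBayes, array weights, all 34 arrays or only the 2 groups in the fit, a replicate block, a replicate block within genotype, and leaving out each array in turn.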

Results

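Gene expression was measured on arrays with Affymetrix Mouse Gene 2.0 ST probe set identifiers in dendritic cells (DCs), the cells that present antigen to T cells, sorted from mouse spleen. Sorted CD8+ DCs, known for cross-presentation to CD8 T cells, and CD8- DCs, known for presentation to CD4 T cells, were profiled by genotype. The genotypes were wild-type (WT) and the label Mst1/2-KO, Mst1 and Mst2 being Hippo kinases, with 4 arrays in each of the 4 groups. Total DCs were profiled on 4 WT and 3 Mst1/2-KO arrays. DCs of Rag1-KO mice, which lack mature T and B cells, were profiled after anti-CD40, an antibody against a co-stimulatory receptor of DCs. Experiment 1 held 4 such Rag1-KO arrays and 3 arrays labelled Rag1-KO p38-KO, p38 being a stress-activated kinase. Experiment 2 held 2 Rag1-KO and 1 WT array after anti-CD40 and 1 non-stimulated Rag1-KO array. The median log2 signal over all probe sets lay between 4.11 and 4.20 per array. Arrays have no read depth, and their number limits the precision. The labels do not say whether the arrays of a group came from separate animals, so each p-value measures only the spread between these arrays. Levels below are means ± SD of log2 signal over the arrays of a group, and changes are log2 differences ± SE. Levels can be compared within an experiment label and not between labels, and every comparison lies within 1 label. The genome build and gene positions are not given in the sources used here.

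The first comparison asked what differs between Mst1/2-KO and WT CD8+ DCs. Stk4, the gene of Mst1 (probe set 17379357), fell 1.81-fold, from 8.33 ± 0.09 in WT to 7.47 ± 0.21 in Mst1/2-KO arrays (n = 4 and 4, adjusted p = 0.000166). Where its probes lie relative to the deletion is not known, and Stk3, the gene of Mst2, is not analysed here. Of the 25 measured DC maturation genes, 11 fell. Ccl22, a chemokine that attracts T cells, fell 5.49-fold (8.26 ± 0.42 against 10.72 ± 0.09, n = 4 and 4, adjusted p = 5.64e-06). Ccr7, the receptor that guides DCs to T cell zones, fell 5.07-fold (7.72 ± 0.60 against 10.07 ± 0.33, adjusted p = 0.000423). All 28 measured genes of the proliferation list were above 0, and 5 were called.

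Of the 25 measured members of the DC maturation and co-stimulation list, 11 fell and 0 rose in CD8+ DCs, and 14 fell when adjusted over the list alone. Il12b, a subunit of the cytokines IL-12 and IL-23, changed by -1.81 ± 0.22 and Socs2, a suppressor of cytokine signalling, by -2.10 ± 0.32. A second Socs2 probe set changed by -0.25 ± 0.11 in CD8+, -0.23 ± 0.11 in CD8- and -0.54 ± 0.13 in total DCs. The list was called lower (median -0.48, adjusted p = 2.65e-22). In the non-canonical NF-kB pathway, 4 of 9 members fell (6 adjusted over the list alone), with Relb at -0.85 ± 0.14 and Nfkb2 at -0.51 ± 0.07. As a whole the list was called lower (median -0.47, adjusted p = 6.12e-10). Among the canonical NF-kB targets, 4 of 14 fell (11 adjusted over the list alone), including Tnfaip3 (-0.93 ± 0.19) and Nfkbia (-0.60 ± 0.11), which encode inhibitors of NF-kB. All 14 members were below 0. As a list they were called lower (median -0.54, adjusted p = 3.65e-15). Relb, Birc3 and Cd40 are on both the maturation and the non-canonical list, and Tnf is on both the maturation and the canonical list. The calls of these lists are therefore not separate evidence, here and in the other comparisons. Of the proliferation genes, 5 of 28 rose (23 adjusted over the list alone). Together the members were called higher (median 0.48, adjusted p = 1.29e-24). Ccna2, which encodes cyclin A2, changed by 0.63 ± 0.13, Top2a by 0.59 ± 0.12, Aurka, a mitotic kinase, by 0.59 ± 0.11 and Birc5, the gene of survivin, by 0.58 ± 0.13. Of 19 ribosome biogenesis genes, 2 rose, Utp20 (0.32 ± 0.07) and Ppan (0.33 ± 0.08), while 7 rose and 1 fell adjusted over the list alone (list median 0.21, adjusted p = 1.69e-06). The other Ppan probe set changed by 0.17 ± 0.19. The unfolded protein response list was called higher with 0 of 17 members called and 4 higher adjusted over the list alone (median 0.15, adjusted p = 0.00072). These 6 lists were also called with an estimated correlation.

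In the same CD8+ comparison, oxidative phosphorylation was called higher with 0 of 69 members called, over all genes or adjusted over the list alone (median 0.09, adjusted p = 5.95e-06). Its adjusted p = 0.302 with an estimated correlation. The lysosome list was called lower with 0 of 17 members called and 4 lower adjusted over the list alone (median -0.12, adjusted p = 0.0011). That list had adjusted p = 0.266 with an estimated correlation. MHC class II presentation was called lower (median -0.05, adjusted p = 0.00428), with H2-Oa, a regulator of peptide loading, lower by -0.47 ± 0.08 and adjusted p = 0.198 with an estimated correlation for the list. Bcl2l11, which encodes the pro-apoptotic protein Bim, fell by 1.17 ± 0.10 on the log2 scale as the only called member of the 14 apoptosis genes (list adjusted p = 0.365). The largest falls outside these lists were in the MHC class Ib gene H2-M2 (-2.79 ± 0.23), Psca (-2.76 ± 0.30), Mreg (-2.73 ± 0.20), Anxa3 (-2.73 ± 0.25), the tetraspanin gene Cd63 (-2.23 ± 0.18), Asprv1 (-2.22 ± 0.19) and the chemokine gene Ccl5 (-2.19 ± 0.16). The largest rises were in Tnfaip8l3 (1.08 ± 0.17), S100a10 (1.03 ± 0.12), the lectin genes Clec4a3 (1.03 ± 0.13), Clec4a1 (0.92 ± 0.17) and Clec4b1 (0.87 ± 0.14), Klra2 (1.02 ± 0.17), Lgals1 (0.96 ± 0.21), the histone genes H2bc18 (0.89 ± 0.18) and H2bc12 (0.77 ± 0.16) and Atp8b4 (0.86 ± 0.14). On the CD8- DC identity list, 1 of 22 members rose, the integrin gene Itgam (0.71 ± 0.14), and 1 fell, Ltb, a tumour necrosis factor family gene (-1.33 ± 0.16; list adjusted p = 0.45). Of the CD8+ DC identity genes, 0 of 21 were called (adjusted p = 0.856). Among the markers of plasmacytoid DCs, T cells, B cells, NK cells, macrophages and neutrophils, 0 members were called. The adjusted p of these 6 lists lay between 0.17 and 0.877.

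Over all 22180 genes, limma called 197 in CD8+ DCs at an adjusted p under 0.05, 52 higher and 145 lower. Of these, 49 changed at least 2-fold (4 higher, 45 lower). Arrays of the 2 genotypes did not overlap for 6.3% of genes, against 2.86% from chance. Quantile normalization gave 70 higher and 171 lower, cyclic loess 61 and 192, and a replicate block or genes above the median gene only 97 and 176. The count was 114 without Mst1/2-KO CD8+ replicate 3 (19 higher, 95 lower) and 126 without replicate 4 (20 and 106). Without replicate 1 or 2 it was 30 higher and 127 lower or 80 and 129, and without WT CD8+ replicate 1 or 2 it was 29 and 121 or 27 and 123. Of the 36 named genes called here, 25 kept their call without each of the 8 arrays. The calls of Tnfaip3, Nfkbia, Lgals1, H2bc18, H2bc12, Itgam, Ccna2, Top2a, Birc5, Utp20 and Ppan ended without some arrays. This held for 10, 10, 5 and 4 of them without WT CD8+ replicates 1, 2, 3 and 4 (adjusted p up to 0.137, 0.112, 0.0996 and 0.0914). It held for 6, 1, 11 and 9 of them without Mst1/2-KO CD8+ replicates 1, 2, 3 and 4 (adjusted p up to 0.133, 0.0775, 0.138 and 0.155). Under other processing settings 15 of the 36 calls ended at least once. Among those kept without each array these were H2-Oa in 2 of 9 settings (adjusted p up to 0.12), Relb (0.0762), Aurka (0.0671) and Clec4a1 (0.0981) in 1 of 9 and Tnfaip8l3 in 1 of 8 (0.0539). Of the others, Ppan lost its call in 4 of 9 (0.378), Lgals1 (0.0724), H2bc12 (0.22), Itgam (0.101), Ccna2 (0.137), Top2a (0.085), Birc5 (0.159) and Utp20 (0.159) in 2, and Tnfaip3 (0.0981) and H2bc18 (0.114) in 1.

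**Figure D1:**
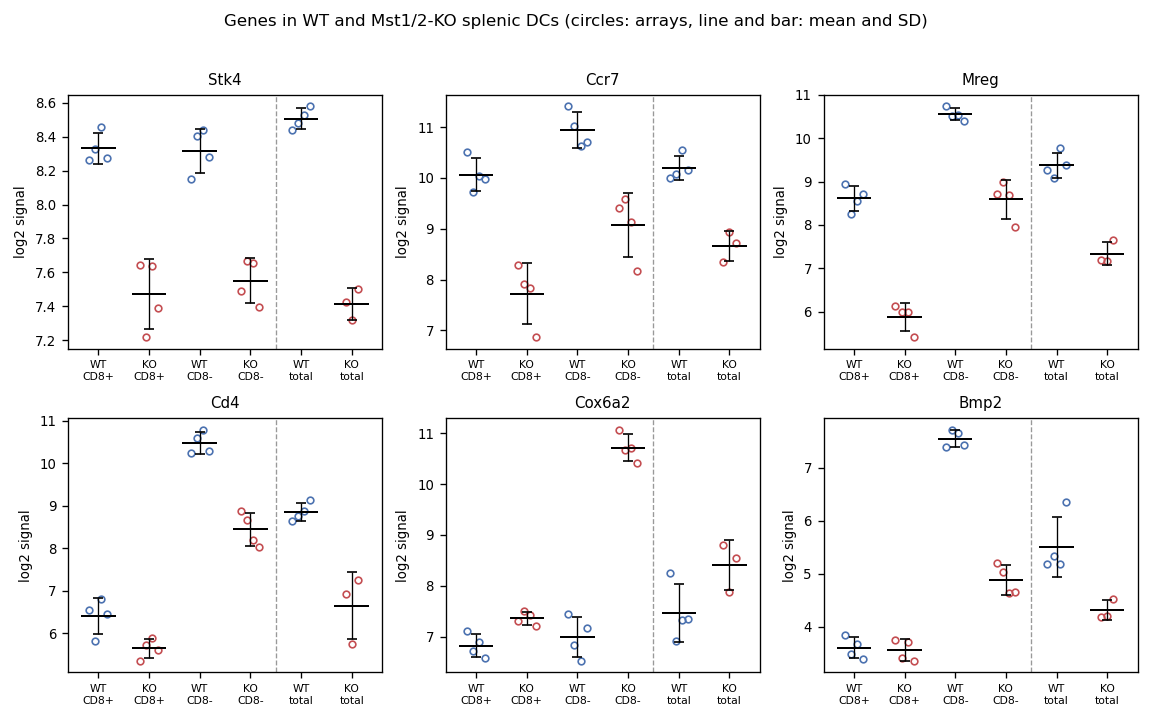
Log2 signal of 6 genes (vertical axes) in WT (blue) and Mst1/2-KO (red) sorted CD8+, sorted CD8- and total DCs; circles are arrays, lines and bars are means and SD, and the dashed line parts experiment labels whose levels cannot be compared. Stk4, Ccr7 and Mreg were lower in every Mst1/2-KO array than in any WT array of the same cells, while Cox6a2 in sorted CD8- DCs stood at 10.72 ± 0.27 in Mst1/2-KO and 6.99 ± 0.40 in WT arrays.

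The same question in CD8- DCs gave changes in more genes. Stk4 fell 1.70-fold, from 8.32 ± 0.13 in WT to 7.55 ± 0.13 in Mst1/2-KO arrays (n = 4 and 4, adjusted p = 0.000211). The largest rise was in Cox6a2, a cytochrome c oxidase subunit on the plasmacytoid DC list, which was 13.3-fold higher (10.72 ± 0.27 against 6.99 ± 0.40, n = 4 and 4, adjusted p = 2.53e-09). Bmp2, a secreted growth factor, was 6.32-fold lower (4.89 ± 0.28 against 7.55 ± 0.16, adjusted p = 9.06e-09). Cd4, a marker of most splenic CD8- DCs, was 4.10-fold lower (8.44 ± 0.40 against 10.48 ± 0.26, adjusted p = 2.53e-05). Of the 25 maturation genes, 13 fell and 1 rose. Of the proliferation and cholesterol synthesis genes 23 of 28 and 11 of 16 rose, but their lists were not called with an estimated correlation (adjusted p = 0.0795 and 0.0606).

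Of the 25 maturation genes, 13 fell in CD8- DCs and 1 rose (17 and 1 adjusted over the list alone), with Ccr7 at -1.86 ± 0.30, Socs2 at -1.59 ± 0.32 and Cd274, the gene of the inhibitory ligand PD-L1, at -1.10 ± 0.22. This list was called lower (median -0.41, adjusted p = 8.42e-12), also with an estimated correlation (adjusted p = 0.00841). Of the proliferation genes, 23 of 28 rose (26 adjusted over the list alone), including Bub1b, a spindle checkpoint kinase (0.80 ± 0.18), and the replication helicase genes Mcm5 (0.76 ± 0.14) and Mcm2 (0.72 ± 0.12). The list was called higher (median 0.58, adjusted p = 5.87e-22), with adjusted p = 0.0795 with an estimated correlation. Of the 16 cholesterol biosynthesis genes, 11 rose (15 adjusted over the list alone), among them Fdps (1.19 ± 0.18), Sqle (0.90 ± 0.16) and Hmgcs1 (0.85 ± 0.16), enzymes of that pathway (list median 0.47, adjusted p = 1.09e-12, and adjusted p = 0.0606 with an estimated correlation). Of the CD8+ DC identity genes, 10 of 21 rose and 2 fell (15 and 4 adjusted over the list alone), including Gcsam (1.19 ± 0.17), Ifi205 (1.02 ± 0.15), Irf8, a transcription factor that CD8+ DCs need (0.91 ± 0.23), and, lower, Ly75, an endocytic receptor (-0.95 ± 0.17). That list was called higher (median 0.55, adjusted p = 1.15e-06), with adjusted p = 0.109 with an estimated correlation. On the CD8- DC identity list, 9 of 22 members fell and 4 rose (10 and 6 adjusted over the list alone). Besides Cd4, these were led by Esam (-1.55 ± 0.14), Tlr5, the flagellin receptor (-1.32 ± 0.17), and the lectin gene Clec10a (1.13 ± 0.20). The list was called lower (median -0.22, adjusted p = 0.0105; adjusted p = 0.125 with an estimated correlation).

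Markers of other cell types moved in this comparison as well. Of the 10 plasmacytoid DC markers, 4 rose, also adjusted over the list alone: Cox6a2, the transcription factor gene Tcf4 (1.08 ± 0.14), Bst2 (1.06 ± 0.16) and Siglech (0.68 ± 0.19). The list was called higher (median 0.37, adjusted p = 1.91e-05; adjusted p = 0.0848 with an estimated correlation). Of the 10 B cell markers, 4 fell, also adjusted over the list alone, with Cr2 (-1.60 ± 0.20), Blk (-1.52 ± 0.25) and Ms4a1, the gene of CD20 (-1.21 ± 0.18). As a list they were called lower (median -0.03, mean -0.42, adjusted p = 0.00791; adjusted p = 0.12 with an estimated correlation). The T cell list was called lower (1 of 11 members, adjusted p = 0.0259), with adjusted p = 0.346 with an estimated correlation. The macrophage and monocyte list was called lower (median -0.23, adjusted p = 0.028; adjusted p = 0.366 with an estimated correlation) with 1 of 16 members lower and 1 higher, Ly6c2, which monocytes and plasmacytoid DCs express (1.94 ± 0.37). Immediate-early and heat-shock genes, which handling can induce, were called lower with 0 of 22 members called (median -0.28, adjusted p = 1.02e-05; adjusted p = 0.193 with an estimated correlation). The NK cell and neutrophil lists were not called (adjusted p = 0.421 and 0.978).

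Among the remaining lists in CD8- DCs, ribosome biogenesis was called higher with 9 of 19 members higher and 1 lower (12 and 1 adjusted over the list alone), including Dkc1 (0.56 ± 0.10) and Utp20 (0.54 ± 0.07; list adjusted p = 2.08e-06; adjusted p = 0.0743 with an estimated correlation). Oxidative phosphorylation was called higher with 6 of 69 members, 8 adjusted over the list alone and Uqcr11 as an example (0.42 ± 0.09; list median 0.11, adjusted p = 5.45e-07; adjusted p = 0.148 with an estimated correlation). Glycolysis (3 of 15 higher and 1 lower, adjusted p = 0.0139; adjusted p = 0.125 with an estimated correlation) and the TCA cycle (1 of 16 higher, adjusted p = 0.028; adjusted p = 0.346 with an estimated correlation) were called higher. The non-canonical NF-kB pathway was called lower with 5 of 9 members lower and 1 higher (Relb at -0.90 ± 0.14; list adjusted p = 0.000131; adjusted p = 0.0743 with an estimated correlation), as were the canonical targets with 3 of 14 lower (adjusted p = 2.48e-05; adjusted p = 0.12 with an estimated correlation) and MHC class II presentation with 2 of 13 lower (adjusted p = 0.0283; adjusted p = 0.244 with an estimated correlation). Of 14 apoptosis genes, 3 rose, with the survival gene Bcl2 at 0.67 ± 0.10 (0.17 ± 0.12 at its other probe set), and the list was not called (adjusted p = 0.0513). The largest other rises were in Dab2, an endocytic adaptor (2.62 ± 0.15), Plcb4, a phospholipase C (2.44 ± 0.14), Alox5, the enzyme that starts leukotriene synthesis (2.41 ± 0.19), Emp1 (2.24 ± 0.51), Pdlim1 (1.85 ± 0.29), Slamf9 (1.80 ± 0.24), Tppp3 (1.79 ± 0.29) and the fatty acid desaturase gene Fads2 (1.76 ± 0.22). The largest other falls were in Mreg (-1.96 ± 0.20), the Notch ligand gene Jag1 (-1.84 ± 0.19), H2-M2 (-1.77 ± 0.23), Gem (-1.74 ± 0.26), Asprv1 (-1.73 ± 0.18), Gpm6b (-1.68 ± 0.18) and Sema7a (-1.67 ± 0.24).

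Of the 22180 genes, limma called 1482 in CD8- DCs, 864 higher and 618 lower, and 169 of them changed at least 2-fold (79 higher, 90 lower). Quantile normalization gave 810 higher and 661 lower, and cyclic loess 761 and 748, without the excess of rises. Groups did not overlap for 12% of genes, against 2.86% from chance. The count was 940 without WT CD8- replicate 2 (504 higher, 436 lower) and 918 without Mst1/2-KO CD8- replicate 4 (514 and 404). Under other settings the calls of Siglech, Irf8 and Emp1 ended in 3, 2 and 1 of 9 (adjusted p up to 0.139, 0.108 and 0.0672). Of 47 named genes, 43 kept their call without each array. The call of Emp1 ended without WT CD8- replicate 2 (adjusted p = 0.0515) and that of Bub1b without Mst1/2-KO CD8- replicate 4 (0.051). The values of Siglech and Irf8 overlapped between the genotypes at the probe sets used. The other probe sets of Irf8 and Emp1 changed by 1.12 ± 0.18 and 1.93 ± 0.32. The call of Irf8 ended without WT CD8- replicate 2 or 3 or Mst1/2-KO CD8- replicate 3 or 4 (adjusted p up to 0.0891). That of Siglech ended without any of these or Mst1/2-KO CD8- replicate 1 (adjusted p up to 0.145). The call of the T cell list ended without WT CD8- replicate 2 or 4 or Mst1/2-KO CD8- replicate 1 (adjusted p up to 0.425). That of the macrophage list ended without WT CD8- replicate 3 or 4 or Mst1/2-KO CD8- replicate 3 (up to 0.184). The call of the TCA cycle list ended without WT CD8- replicate 2 or 4 or Mst1/2-KO CD8- replicate 3 or 4 (up to 0.0836). That of MHC class II presentation ended without Mst1/2-KO CD8- replicate 3 or 4 (up to 0.0794).

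Whether the Mst1/2-KO effect differed between the subsets was tested as the change in CD8+ DCs minus the change in CD8- DCs. The effect on Stk4 itself did not pass this test (-0.09 ± 0.14, adjusted p = 0.913). The difference was negative for Cox6a2 (-3.19 ± 0.24), Alox5 (-2.54 ± 0.27) and Dab2 (-2.39 ± 0.21), which rose in CD8- DCs. It was positive for Bmp2 (2.62 ± 0.20), Gpm6b (1.57 ± 0.25) and Tlr5 (1.43 ± 0.24). Ccl22 (-2.18 ± 0.31) and Bcl2l11 (-1.13 ± 0.15) fell more in CD8+ DCs. Esam (1.09 ± 0.20), Cr2 (1.57 ± 0.28), Sucnr1, a succinate receptor gene (1.55 ± 0.27), Tcf4 (-1.16 ± 0.20) and Tnip3, whose product binds the NF-kB inhibitor A20 (-2.15 ± 0.39), also differed. In WT CD8+ DCs Bmp2 stood at 3.60, Sucnr1 at 2.97, Cr2 at 3.80 and Gpm6b at 4.30, near or below the medians of the 22180 tested genes per array (4.31 or above). The values carry a constant per probe set, so a level set against these medians is only a rough guide to background. If these 4 genes lie near background, they had little room to fall in CD8+ DCs. Their differences therefore do not show an effect limited to CD8- DCs. Of the 49 genes with a positive difference, 10 had means below these medians in CD8+ DCs of both genotypes.

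Of the cholesterol biosynthesis genes, 0 of 16 passed this test singly and 11 did when adjusted over the list alone, all lower. Together the members were called lower (median -0.47, adjusted p = 1.25e-09; adjusted p = 0.0874 with an estimated correlation). Of the CD8+ DC identity genes, 1 of 21 was lower (8 adjusted over the list alone). This list was called lower (median -0.54, adjusted p = 1.82e-06; adjusted p = 0.19 with an estimated correlation). All 10 plasmacytoid DC markers were below 0, 2 of them called (5 adjusted over the list alone; median -0.55, adjusted p = 8.71e-09), and the apoptosis list was called lower with Bcl2l11 as its called member (median -0.16, adjusted p = 0.00159). Both of these were called with an estimated correlation as well (adjusted p = 0.0408 for each). The immediate-early and heat-shock list was called higher with 0 of 22 members called (median 0.21, adjusted p = 0.00159; adjusted p = 0.534 with an estimated correlation). Its call ended without WT CD8+ replicate 3 or Mst1/2-KO CD8- replicate 3 (adjusted p up to 0.0724). The maturation list was not shown to differ between the subsets, with 2 of 25 members lower (adjusted p = 0.178).

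This test of the difference called 124 genes, 49 higher and 75 lower, and 2030 genes had an unadjusted p under 0.05. Within each genotype the CD8+ and CD8- arrays of 1 replicate number shared their deviations from the group mean, and a fit with a replicate block within genotype called 211 genes (72 higher, 139 lower), 107 of them among the 124, and 7 lists instead of 5. The count was 259 without WT CD8- replicate 1 (104 higher, 155 lower), 79 without WT CD8- replicate 2 (34 and 45) and 80 without Mst1/2-KO CD8- replicate 4 (30 and 50). The number of lists was 8 without WT CD8+ replicate 1, WT CD8- replicate 2 or Mst1/2-KO CD8+ replicate 4, and 9 without WT CD8- replicate 1 or Mst1/2-KO CD8- replicate 4.

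**Figure D2:**
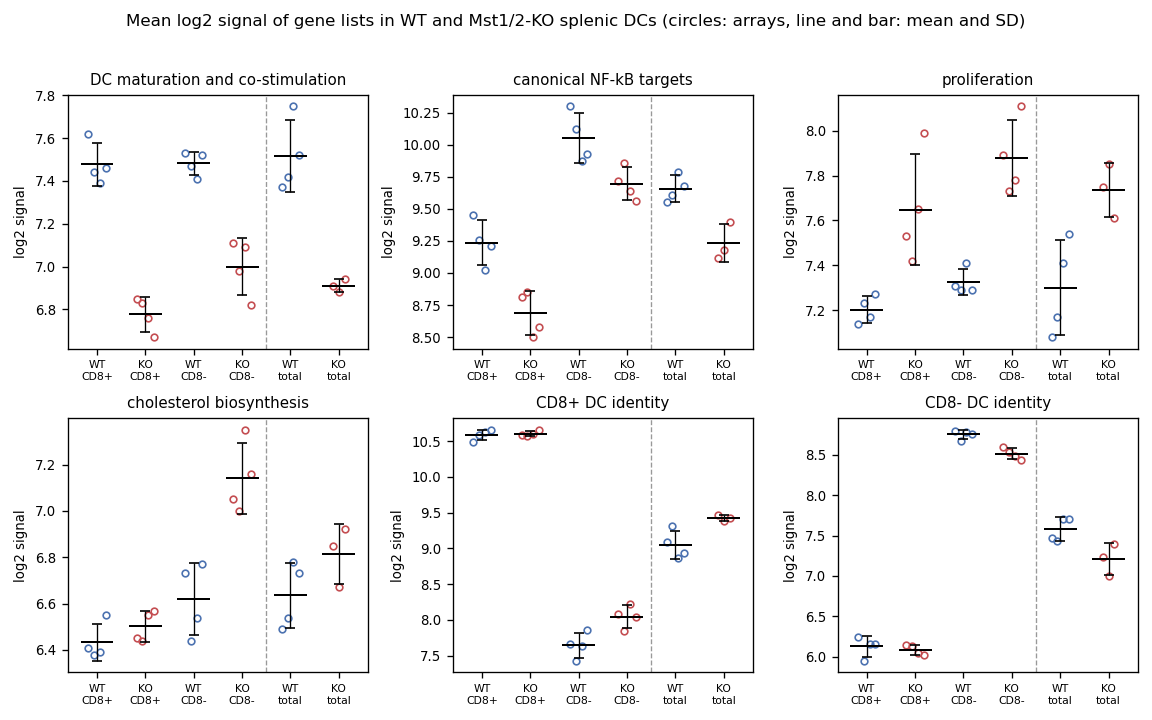
Mean log2 signal over the measured members of 6 gene lists (vertical axes) in WT (blue) and Mst1/2-KO (red) DCs; circles are arrays, lines and bars are means and SD, and the dashed line parts experiment labels whose levels cannot be compared. The maturation list was lower in Mst1/2-KO than in WT arrays by a mean of 0.70 in CD8+, 0.48 in CD8- and 0.60 in total DCs, and the CD8+ DC identity list lay at 8.05 against 7.65 in CD8- and 9.43 against 9.05 in total DCs.

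Total DCs, a mixture of the subsets, gave a comparison of the genotypes under a separate experiment label. Stk4 fell 2.13-fold, from 8.51 ± 0.06 in WT to 7.41 ± 0.09 in Mst1/2-KO arrays (n = 4 and 3, adjusted p = 0.00154). H2-M2 fell 5.39-fold (-2.43 ± 0.20, adjusted p = 0.00154). Cd4 fell 4.60-fold (6.65 ± 0.78 against 8.85 ± 0.21, adjusted p = 0.0123). Plcb4 rose 3.21-fold (6.74 ± 0.04 against 5.06 ± 0.20, adjusted p = 0.00105). In total DCs 7 of the 25 maturation genes fell, among them Ccr7 at -1.53 ± 0.17, Il12b at -1.41 ± 0.20 and Fscn1, which encodes an actin-bundling protein of mature DCs, at -1.31 ± 0.21. Their list had adjusted p = 0.136 with an estimated correlation, and the calls of Il12b and Fscn1 ended without 2 and 4 of the 7 arrays (adjusted p up to 0.0911 and 0.127).

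Of the 25 maturation genes, 7 fell and 0 rose in total DCs (14 adjusted over the list alone). The list was called lower (median -0.48, adjusted p = 4.05e-15; adjusted p = 0.136 with an estimated correlation). The non-canonical NF-kB pathway was called lower with 1 of 9 members called, Birc2 (-0.74 ± 0.09; list adjusted p = 1.52e-06), as were the canonical targets with 1 of 14 (adjusted p = 2.78e-08), and both had adjusted p = 0.136 with an estimated correlation. Of the proliferation genes, 0 of 28 passed the test singly and 23 did when adjusted over the list alone, all higher. As a list they were called higher (median 0.45, adjusted p = 6.66e-16; adjusted p = 0.271 with an estimated correlation). Ribosome biogenesis was called higher with 2 of 19 members, Srm (0.58 ± 0.10) and Cad (0.54 ± 0.10), and 7 adjusted over the list alone (adjusted p = 2.04e-08; adjusted p = 0.136 with an estimated correlation). Oxidative phosphorylation was called higher with 0 of 69 members called (median 0.14, adjusted p = 3.5e-07), also with an estimated correlation (adjusted p = 0.0296). Of the CD8+ DC identity genes, 2 of 21 rose, Rab7b (0.81 ± 0.13) and Plpp1 (0.73 ± 0.12), 10 did adjusted over the list alone. Together the members were called higher (median 0.42, adjusted p = 1.91e-10; adjusted p = 0.271 with an estimated correlation). The CD8- DC identity list was called lower (median -0.41, adjusted p = 0.000533, and adjusted p = 0.348 with an estimated correlation). Cd4 and Tlr7, a receptor for single-stranded RNA (-1.69 ± 0.27), were its 2 called members of 22. In this mixture, other shares of the subsets and a change within a subset cannot be told apart from the identity lists.

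Markers of other cells in total DCs were lower for B cells (0 of 10 members called, adjusted p = 0.00572; adjusted p = 0.136 with an estimated correlation), plasmacytoid DCs (0 of 10, adjusted p = 0.0149; adjusted p = 0.49 with an estimated correlation) and macrophages (1 of 16, Adgre1, the gene of F4/80, at -1.47 ± 0.22; list adjusted p = 0.018; adjusted p = 0.49 with an estimated correlation). The lists of T cell (median 0.09, mean -0.03, adjusted p = 0.841), NK cell (0.516), neutrophil (0.565) and immediate-early genes (0.472) were not called. Interferon-stimulated genes (median -0.32, adjusted p = 5.84e-05; adjusted p = 0.348 with an estimated correlation) and lysosome genes (adjusted p = 0.00572; adjusted p = 0.404 with an estimated correlation) were called lower with 0 members called. The TCA cycle (adjusted p = 0.000275; adjusted p = 0.348 with an estimated correlation), cholesterol biosynthesis (adjusted p = 0.00572; adjusted p = 0.49 with an estimated correlation) and the unfolded protein response (adjusted p = 0.0265; adjusted p = 0.348 with an estimated correlation) were called higher with 0 members called. The largest other falls were in Mreg (-2.04 ± 0.18), Asprv1 (-1.90 ± 0.12), Gbp4 (-1.71 ± 0.25), Socs2 (-1.66 ± 0.29), Anxa3 (-1.65 ± 0.18), H2-Eb2 (-1.62 ± 0.21) and Ifit1bl1 (-1.59 ± 0.16). The largest other rises were in Pigr, which carries immunoglobulin A across epithelia (1.47 ± 0.17), Alox5 (1.42 ± 0.21), the integrin gene Itgad (1.41 ± 0.22), Serpinb8 (1.23 ± 0.21), Tppp3 (1.16 ± 0.21), Septin3 (1.14 ± 0.17), Met, the receptor of hepatocyte growth factor (1.08 ± 0.17), Mboat1 (0.92 ± 0.11) and Ccnyl1 (0.89 ± 0.12).

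In total DCs limma called 188 genes, 70 higher and 118 lower. Of these, 67 changed at least 2-fold (9 higher, 58 lower). Quantile normalization gave 72 higher and 190 lower, and cyclic loess 68 higher and 201 lower. Groups did not overlap for 13.8% of genes, against 5.71% from chance. The count was 118, 124 and 89 without WT total replicates 2, 3 and 4, and 53 (12 higher, 41 lower) and 39 (6 and 33) without Mst1/2-KO total replicates 1 and 2. In 1 of 8 other settings the calls of Alox5, Serpinb8, Tppp3, Mboat1, Ccnyl1, Srm, Cad, Plpp1 and Rab7b ended (adjusted p up to 0.124). Of 30 named genes, 11 kept their call without each of the 7 arrays. The calls of Tlr7, Socs2, Alox5, Itgad, Serpinb8, Tppp3, Septin3, Met, Mboat1, Ccnyl1, Il12b, Fscn1, Birc2, Srm, Cad, Plpp1, Rab7b and Adgre1 ended without Mst1/2-KO total replicate 2 (adjusted p up to 0.162) and that of H2-Eb2 without replicate 1 (0.0632). Without Mst1/2-KO total replicates 1 and 3, 13 and 9 of the 30 calls ended (adjusted p up to 0.146 and 0.117). Without WT total replicates 1, 2, 3 and 4, the number was 5, 6, 7 and 13 (up to 0.0813, 0.0909, 0.0789 and 0.0964). The list calls of plasmacytoid DC markers, B cell markers, macrophage markers, cholesterol biosynthesis, lysosome and the unfolded protein response also ended without 1 array. The arrays were WT replicates 1 and 3 and Mst1/2-KO replicates 2 and 3 for plasmacytoid DCs (adjusted p up to 0.143), Mst1/2-KO replicate 2 for B cells (0.0569), WT replicates 1 and 2 and Mst1/2-KO replicates 2 and 3 for macrophages (up to 0.173), WT replicate 1 and Mst1/2-KO replicate 3 for cholesterol (up to 0.085), WT replicate 3 and Mst1/2-KO replicate 2 for lysosome (up to 0.0888), and WT replicates 2 and 4 and Mst1/2-KO replicates 2 and 3 for the unfolded protein response (up to 0.0837).

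The sorted and the total comparison share no array. Of the 118 genes lower in Mst1/2-KO total DCs, 44 were also lower in CD8+ DCs, where 0.77 would be expected if the calls were independent (Fisher's exact p = 2.04e-67). In CD8- DCs, 87 were lower (3.29 expected, Fisher's exact p = 1.37e-110). Of the 70 genes higher in total DCs, 5 were higher in CD8+ DCs (0.16 expected, Fisher's exact p = 6.27e-07) and 49 in CD8- DCs (2.73 expected, Fisher's exact p = 4.06e-53). These p-values treat genes as independent. Between the sorted subsets, 73 genes were lower in both and 38 higher in both. No expected number is given for these, because CD8+ and CD8- arrays of 1 genotype and number share deviations, so the 2 comparisons are not independent. In all 3 comparisons 37 genes were called in the same direction, 33 lower, among them Stk4, Ccr7, Mreg, H2-M2, Asprv1 and Socs2, and 4 higher, namely Plcb4, S100a10, Atp8b4 and 4931431B13Rik, the last chosen after its values were seen. The YAP/TAZ target genes, which the Hippo pathway restrains, were not called as a list in CD8+ (adjusted p = 0.45), CD8- (0.662) or total DCs (0.336), nor were the other Hippo pathway components (adjusted p = 0.544, 0.421 and 0.516).

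The 2 subsets were compared in WT mice to describe the sorted populations. Cd8a, which encodes the chain of CD8 used for the sort, was 43.1-fold higher in CD8+ DCs (12.12 ± 0.09 against 6.69 ± 0.30, n = 4 and 4, adjusted p = 2.3e-12). Clec4a4, the gene of the CD8- DC lectin DCIR2, was 66.4-fold lower (4.92 ± 0.37 against 10.97 ± 0.23, adjusted p = 3.39e-13). All 21 CD8+ DC identity genes were higher (median 2.99, adjusted p = 2.87e-35), led by Cd8a, Gcsam (5.12 ± 0.17), Itgae, the gene of CD103 (4.86 ± 0.21), and Plpp1 (4.34 ± 0.16). Of the CD8- DC identity genes, 20 of 22 were lower and 1 was higher (median -2.79, adjusted p = 1.67e-29), with Tlr7 at -4.86 ± 0.22 and Cd4 at -4.07 ± 0.21. Stk4 stood at 8.33 ± 0.09 and 8.32 ± 0.13 (adjusted p = 0.956).

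Interferon-stimulated genes were lower in CD8+ than in CD8- DCs in 19 of 26 members and higher in 4, with Rtp4 at -4.29 ± 0.25 and Oas2, a sensor of double-stranded RNA, at -3.49 ± 0.31. This list was called lower (median -0.93, adjusted p = 2.92e-09; adjusted p = 0.156 with an estimated correlation). Of the canonical NF-kB targets, 11 of 14 were lower (median -0.78, adjusted p = 6.01e-08; adjusted p = 0.0534 with an estimated correlation). The non-canonical pathway was lower in 5 of 9 members and higher in 1 (adjusted p = 0.000585; adjusted p = 0.0564 with an estimated correlation). The maturation list went both ways, with 6 of 25 members higher and 6 lower (adjusted p = 0.394). Il12b (2.48 ± 0.22) and Ccl22 (2.71 ± 0.22) were higher in CD8+ DCs and Cd274 was lower (-2.48 ± 0.22). Presentation by MHC class I was higher in 9 of 18 members and lower in 3, with the peptide transporter genes Tap1 (1.00 ± 0.08) and Tap2 (1.23 ± 0.09) higher (list adjusted p = 0.019; adjusted p = 0.161 with an estimated correlation). MHC class II presentation was not called as a list, with 3 of 13 members higher and 4 lower (adjusted p = 0.0665). The unfolded protein response was higher in 9 of 17 members and lower in 1 (median 0.33, adjusted p = 0.000208), also with an estimated correlation (adjusted p = 0.0269). Oxidative phosphorylation was higher in 25 of 69 (adjusted p = 3.37e-07; adjusted p = 0.161 with an estimated correlation). Glycolysis was higher in 6 of 15 and lower in 3, with Pfkp at 1.66 ± 0.15 and Pgk1 at 1.18 ± 0.09 (adjusted p = 0.0483; adjusted p = 0.204 with an estimated correlation). Ribosome biogenesis was higher in 7 of 19 (adjusted p = 0.00643; adjusted p = 0.163 with an estimated correlation).

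Further lists separated the WT subsets. Integrins and migration receptors were lower in CD8+ DCs in 9 of 19 members and higher in 4 (adjusted p = 0.00632; adjusted p = 0.0562 with an estimated correlation). Immediate-early and heat-shock genes were lower in 10 of 22 (adjusted p = 1.98e-06; adjusted p = 0.161 with an estimated correlation), lysosome genes lower in 8 of 17 and higher in 4 (adjusted p = 0.00632; adjusted p = 0.207 with an estimated correlation), and p38 MAPK pathway genes lower in 8 of 13 and higher in 3 (adjusted p = 0.0248; adjusted p = 0.161 with an estimated correlation). Cholesterol biosynthesis was lower in 5 of 16 and higher in 2 (adjusted p = 0.019; adjusted p = 0.352 with an estimated correlation). Proliferation was lower in 5 of 28 and higher in 1 (adjusted p = 0.0425; adjusted p = 0.653 with an estimated correlation). Markers of other cells were lower in CD8+ DCs for T cells (10 of 11, with Il7r at -2.93 ± 0.26 and Cd3e at -1.66 ± 0.24; adjusted p = 4.07e-08) and NK cells (7 of 9, with Klrd1 at -4.70 ± 0.20; adjusted p = 5.34e-06). Both kept their call with an estimated correlation (adjusted p = 0.048 for each). They were also lower for macrophages (11 of 16, adjusted p = 1.35e-07; adjusted p = 0.0562 with an estimated correlation), plasmacytoid DCs (4 of 10 lower and 1 higher, adjusted p = 0.0162; adjusted p = 0.209 with an estimated correlation) and B cells (4 of 10 lower and 2 higher, adjusted p = 0.0248; adjusted p = 0.161 with an estimated correlation). The neutrophil list was not called (adjusted p = 0.0803). The lists of YAP/TAZ targets (adjusted p = 0.677), Hippo components (0.792), TCA cycle (0.544), mitochondrial dynamics and biogenesis (0.868) and apoptosis (0.77) were not called. The largest other differences were higher in CD8+ DCs for Clec4b2 (5.18 ± 0.31), Ctla2b (4.74 ± 0.18), P3h2 (4.68 ± 0.18), Cd207, the gene of langerin (4.60 ± 0.17), Pdia5 (4.39 ± 0.19) and Hepacam2 (4.37 ± 0.22). They were lower for Sirpb1c (-4.99 ± 0.18), Clec4a1 (-4.93 ± 0.17), Bex6 (-4.85 ± 0.24), Sh2d1b1 (-4.74 ± 0.16), Cd7 (-4.62 ± 0.24), the macrophage metalloelastase gene Mmp12 (-4.58 ± 0.22) and Sirpb1a (-4.57 ± 0.17).

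For the WT subsets limma called 4663 genes, 2444 higher and 2219 lower in CD8+ DCs, and 1075 of them differed at least 2-fold (451 higher, 624 lower). Quantile normalization gave 2610 higher and 2174 lower, but cyclic loess 2225 higher and 2511 lower. Groups did not overlap for 22.4% of genes, against 2.86% from chance. A replicate block within genotype gave 5040 genes. Some list calls ended without 1 array. They were glycolysis without any WT CD8+ replicate or WT CD8- replicate 2 or 3 (adjusted p up to 0.0857), cholesterol biosynthesis without WT CD8- replicate 1 or 4 (up to 0.0594), proliferation without WT CD8+ replicate 1 or 3 or WT CD8- replicate 1 or 3 (up to 0.0897) and the p38 MAPK pathway without WT CD8- replicate 1 (0.0528).

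Arrays of anti-CD40-stimulated DCs in experiment 1 compared the label Rag1-KO p38-KO with Rag1-KO. The labels do not say which p38 gene was deleted. Mapk14, the gene of p38alpha (probe set 17335364), stood at 8.47 ± 0.08 in the arrays labelled Rag1-KO p38-KO and 8.24 ± 0.26 in Rag1-KO arrays (n = 3 and 4, adjusted p = 0.657). Mapk11, the gene of p38beta, stood at 5.14 ± 0.12 and 5.37 ± 0.09 (adjusted p = 0.556). Where the probes lie relative to a deletion is not known. No gene passed the test. The 5 genes with the smallest p, each with adjusted p = 0.141, were Plcb4 (3.64-fold higher, 6.94 ± 0.16 against 5.07 ± 0.28), Zmynd15 (-0.69 ± 0.07), Rgs1, a regulator of G protein signalling (-0.58 ± 0.06), the autophagy receptor gene Sqstm1 (-0.65 ± 0.07) and Gclc, which makes the glutathione precursor (-1.44 ± 0.15).

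As lists, several groups were lower in the arrays labelled Rag1-KO p38-KO, although none was called with an estimated correlation. All 25 maturation genes were below 0, with 10 lower adjusted over the list alone, Il12b at -1.86 ± 0.33 and Ccr7 at -1.12 ± 0.14 (median -0.59, adjusted p = 1.56e-14; adjusted p = 0.374 with an estimated correlation). All 26 interferon-stimulated genes were below 0, with 0 adjusted over the list alone, Cxcl10, a chemokine gene, at -2.25 ± 0.51 and Oasl1 at -2.08 ± 0.84 (median -0.84, adjusted p = 8.36e-10; adjusted p = 0.582 with an estimated correlation). All 12 neutrophil and granule markers were below 0, with 3 adjusted over the list alone, Ltf, the gene of lactoferrin, at -1.92 ± 0.49 and Ly6g at -0.55 ± 0.12 (median -1.21, adjusted p = 3.48e-09; adjusted p = 0.374 with an estimated correlation). Macrophage markers (median -0.65, adjusted p = 2.77e-05; adjusted p = 0.582 with an estimated correlation) and the canonical (adjusted p = 5.56e-05) and non-canonical NF-kB lists (adjusted p = 0.00303), both with adjusted p = 0.374 with an estimated correlation, were called lower. The unfolded protein response (adjusted p = 0.000377; adjusted p = 0.374 with an estimated correlation), cholesterol biosynthesis (adjusted p = 0.00375; adjusted p = 0.582 with an estimated correlation), immediate-early genes (adjusted p = 0.0108; adjusted p = 0.59 with an estimated correlation) and MHC class I presentation (adjusted p = 0.0461; adjusted p = 0.742 with an estimated correlation) were called lower. CD8- DC identity was called higher (adjusted p = 0.0499; adjusted p = 0.627 with an estimated correlation). The p38 MAPK pathway genes other than Mapk14 were not called as a list (adjusted p = 0.617).

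The 4 Rag1-KO arrays of experiment 1 fell into pairs. Mean signals of the interferon-stimulated genes were 6.36 and 6.47 in replicates 1 and 2 and 8.40 and 7.78 in replicates 3 and 4, against 6.08, 6.17 and 6.39 in the arrays labelled Rag1-KO p38-KO. For DC maturation and co-stimulation they were 7.09 and 7.16, then 8.10 and 7.87, against 6.56, 6.57 and 6.94. Without replicates 3 and 4, a setting chosen after seeing the data, the median change was -0.10 for interferon-stimulated genes (adjusted p = 0.000972; adjusted p = 0.671 with an estimated correlation) and -0.32 for maturation genes (adjusted p = 4.43e-08; adjusted p = 0.669 with an estimated correlation), with 0 genes called. Without replicates 1 and 2, also chosen after seeing the data, the medians were -1.67 and -0.89, with 85 genes called. The adjusted p of camera was 4.26e-26 and 9.14e-18, and 0.41 for each with an estimated correlation. The arrays left out in both settings were picked by their interferon-stimulated genes. Neither setting is therefore a test of that list, and the values only describe how far the result depends on the pairs.

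With all 7 arrays limma called 0 genes, while 1866 had an unadjusted p under 0.05. The count was also 0 with a replicate block, which fits the numbering of these arrays, and was 209 with the spread taken from all 34 arrays. Groups did not overlap for 7.5% of genes, against 5.71% from chance. With the replicate block, 10 lists were called instead of 11, without MHC class I presentation (adjusted p = 0.171) and CD8- DC identity (0.57) and with oxidative phosphorylation higher (0.00212). Up to 11.2% of genes in the Rag1-KO group and 11.8% in the other group had exactly the same value on 2 arrays, against at most 0.12% in the other groups. The calls of CD8- DC identity and MHC class I presentation ended without Rag1-KO replicate 3 or 4 or Rag1-KO p38-KO replicate 2, the former also without Rag1-KO p38-KO replicate 3 (adjusted p up to 0.431) and the latter also without replicate 1 (up to 0.288). The call of cholesterol biosynthesis ended without Rag1-KO p38-KO replicate 1 (0.103), and that of immediate-early genes without that array or Rag1-KO replicate 2 (up to 0.288).

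**Figure D3:**
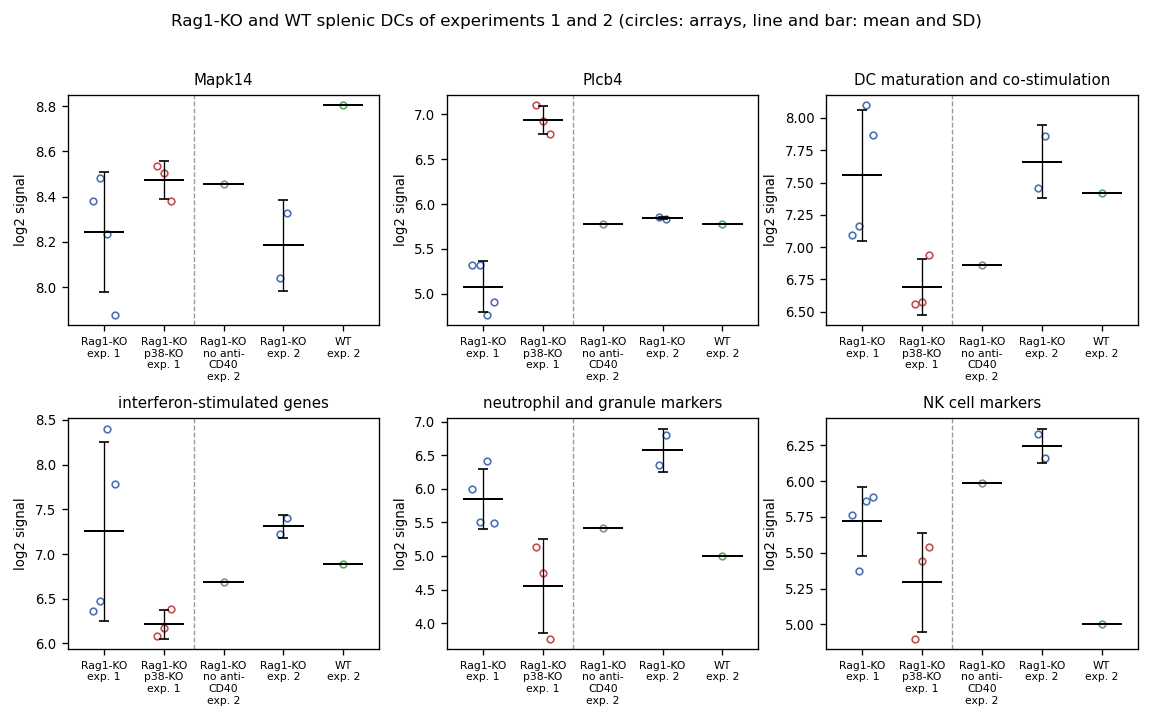
Log2 signal of Mapk14 and Plcb4 and mean log2 signal over 4 gene lists (vertical axes) in DCs of experiments 1 and 2; circles are arrays, lines and bars are means and SD where a group has more than 1 array, colours mark the groups named on the horizontal axis, and the dashed line parts the experiments, whose levels cannot be compared. Mapk14 was not lower in the arrays labelled Rag1-KO p38-KO (8.47 ± 0.08 against 8.24 ± 0.26), and the maturation list of the Rag1-KO arrays of experiment 1 lay at 7.09 to 8.10.

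The effect of anti-CD40 was compared in experiment 2 on 2 stimulated Rag1-KO arrays and 1 non-stimulated Rag1-KO array, so the lone array was assumed to vary like the others. Of the 25 maturation genes, 24 were above 0 and 0 were called, with 1 called adjusted over the list alone. The list was called higher (median 0.79, adjusted p = 2.75e-07; adjusted p = 0.986 with an estimated correlation). Ccl17, a T cell chemokine gene, stood at 6.51 ± 0.26 against 4.31, Cd40 at 8.78 ± 0.19 against 6.97, Ccl22 at 9.86 ± 0.36 against 8.32 and the co-stimulatory ligand gene Tnfsf9 at 9.21 ± 0.11 against 7.96. The neutrophil list was called higher with 11 of 12 members above 0 (median 1.16, adjusted p = 0.000598), with Retnlg at 6.67 ± 0.39 against 3.17 and Cxcr2 at 7.11 ± 1.08 against 4.83. CD8+ DC identity (adjusted p = 0.000136), proliferation (0.000598), canonical (0.00634) and non-canonical NF-kB (0.00634) and interferon-stimulated genes (0.00886) were called higher too, and these 7 lists had adjusted p = 0.986 with an estimated correlation.

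No gene named for this comparison was called. Stfa2l1 (2.63 ± 0.77), Slfn4 (2.57 ± 1.19) and Tarm1 (2.36 ± 0.63) were higher and Ace, the angiotensin-converting enzyme gene (-1.79 ± 0.46), Ctrb1 (-1.50 ± 0.93), Lrrc8d (-1.45 ± 0.58), Apoc2 (-1.44 ± 0.42) and Fabp4 (-1.41 ± 0.62) lower in the stimulated arrays. Over the 22180 genes, limma called 8, 6 higher and 2 lower, and 6 higher and 1 lower after quantile or cyclic loess normalization, with 2908 genes at an unadjusted p under 0.05. The count was 39 (15 higher, 24 lower) without Rag1-KO anti-CD40 replicate 1 and 136 (80 and 56) without replicate 3, and 0 with a replicate block. Groups did not overlap for 70.0% of genes, against 66.67% from chance.

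Rag1-KO DCs after anti-CD40 were compared with WT DCs in experiment 2 on 2 arrays against 1, under the same assumption. Genes of B cells, which Rag1-KO mice lack, were lower: Jchain, which joins immunoglobulin polymers, stood at 2.72 ± 0.07 against 4.71 (adjusted p = 0.00017), Fcer2a, the gene of CD23, at 3.85 ± 0.05 against 5.47 (adjusted p = 0.0133), Cd79a at 2.94 ± 0.33 against 4.45 (adjusted p = 0.0404) and Ms4a1 at 5.10 ± 0.41 against 6.45 (adjusted p = 0.047). Of the 10 B cell markers, 2 fell (3 adjusted over the list alone). As a list they were called lower (median -0.43, adjusted p = 0.00112; adjusted p = 0.283 with an estimated correlation). Cd3e, a T cell receptor subunit gene, fell by 1.21 ± 0.15 on the log2 scale as 1 of 11 T cell markers (list adjusted p = 0.201). Sucnr1 fell by 1.71 ± 0.22. Under other settings the call ended for Ms4a1 in 6 of 8 (adjusted p up to 0.266), Cd3e in 3 of 8 (0.569), Cd79a in 2 of 7 (0.266), Fcer2a in 2 of 7 (0.159), Sucnr1 in 1 of 7 (0.249) and Jchain in 1 of 7 (0.0918). Rag1 itself is not analysed here, because its probe set is shared with another gene.

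All 9 NK cell markers were above 0 in the Rag1-KO arrays, with 0 called and 6 adjusted over the list alone. Together the members were called higher (median 1.29, adjusted p = 0.000125; adjusted p = 0.388 with an estimated correlation). The granzyme gene Gzmb stood at 5.99 ± 0.30 against 3.59, Ncr1, an NK cell receptor gene, at 7.10 ± 0.38 against 4.72, Gzma at 5.27 ± 0.10 against 3.49 and Nkg7 at 7.50 ± 0.34 against 5.84. All 12 neutrophil markers were above 0, with 6 adjusted over the list alone (median 1.53, adjusted p = 0.000125; adjusted p = 0.546 with an estimated correlation). Among them, the granule protein genes Camp stood at 7.11 ± 0.20 against 3.86 and Ngp at 7.20 ± 0.19 against 4.47, and Retnlg at 6.67 ± 0.39 against 4.14. Cholesterol biosynthesis (adjusted p = 0.000653; adjusted p = 0.546 with an estimated correlation), the TCA cycle (adjusted p = 0.00193; adjusted p = 0.283 with an estimated correlation), immediate-early genes (adjusted p = 0.0362; adjusted p = 0.766 with an estimated correlation), with the heat-shock gene Hspa1b at 9.78 ± 0.50 against 11.40, and MHC class II presentation (adjusted p = 0.0478; adjusted p = 0.66 with an estimated correlation) were called lower. Gzmc (3.04 ± 0.72), Slfn4 (2.68 ± 1.19) and the lysozyme gene Lyz1 (-2.01 ± 0.72) were not called.

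Here limma called 81 genes, 54 higher and 27 lower in Rag1-KO arrays. Of these, 32 changed at least 2-fold (17 higher, 15 lower). The count was 195 without Rag1-KO anti-CD40 replicate 1 (137 higher, 58 lower), 234 without replicate 3 (163 and 71) and 2 with a replicate block, and the call of Cd79a ended without replicate 3 (adjusted p = 0.0606). Groups did not overlap for 71.7% of genes, against 66.67% from chance.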

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

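The tests of handling, of fewer mature cells, of plasmacytoid DCs, of a smaller CD8+ DC share over all list members, of splits after removal of the common genotype effect and of splits that keep the pairs were chosen after the results were seen. The fall of maturation genes in Mst1/2-KO DCs (mean -0.70, -0.48 and -0.60 in CD8+, CD8- and total DCs) could come from less activation during handling, from normalization or from fewer mature cells. In CD8+ DCs the immediate-early and heat-shock list changed by -0.05 (95% interval -0.34 to 0.23). The interval only just clears 0.5 of the fall of the maturation genes (-0.35), a limit set after the results were seen. So small a margin leaves handling open there. In CD8- DCs the list changed by -0.31 (-0.57 to -0.05), as far as handling would need. In total DCs it changed by -0.02 (-0.32 to 0.29), which leaves handling open. Of 10000 random lists matched on the deposited signal, 0% had a median as low in CD8+ DCs (lowest -0.13 against -0.48). This argues against a normalization that depends on that signal. The deposited signal carries a constant per probe set, so it is only a rough guide to the level at which the normalization acted. With 18.2% of the WT level left at Ccl22, a smaller share of mature cells and lower expression per cell cannot be told apart, since the arrays hold no cell counts, and an effect of the genotype stays open. In the sorted cells a difference in the sex of the animals stays open too, as the sex-linked genes moved with genotype.

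The rise of CD8+ and plasmacytoid DC genes in Mst1/2-KO CD8- DCs could come from such cells in the sort. The 31 genes at least 8-fold higher in CD8+ DCs changed by a median of 0.52 (quartiles 0.07 to 0.75), 25 of them upward, where the share of CD8+ DCs implied by the called identity genes (median 9.74%) needs 0.94 to 1.57, and Cd8a changed by 0.69 where 2.34 was needed. The called genes were picked because they rose, which raises the share they imply. The 8-fold genes were picked partly by their level in Mst1/2-KO CD8- DCs, which favours genes that stayed low there. The gap between the observed and the needed changes therefore decides nothing. With a share of 1.70%, as the 8-fold genes imply, 11 of all 21 measured members lay over 2 SE above what it gives and 4 below. The 10 of 10 called members above it were picked because they rose, which decides nothing either. A share of CD8+ DCs in the sort therefore stays open. The other 9 plasmacytoid markers changed by a median of 0.21 with 3 called higher, so plasmacytoid DCs and a change within CD8- DCs cannot be told apart, and the genotype effect stays open.

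Other splits of the arrays called fewer genes than the real one in CD8+ DCs (1 of 35 splits as many, 197 against at most 3), CD8- DCs (1 of 35, 1482 against 32), WT subsets (1 of 35, 4663 against 2) and total DCs (1 of 35, 188 against 2). A share of 1 in 35 is the smallest that these splits can give. It makes chance unlikely in CD8+, CD8- and total DCs only if the arrays are independent, which the labels do not say. WT CD8+ and CD8- arrays of 1 replicate number share deviations, and these splits break such pairs. Only 8 splits of the WT subsets part all pairs, too few for a share under 0.05 (4663 against at most 0), so the splits do not exclude chance there. In experiment 1 the real split called 0 genes, so all 35 of 35 splits had to call as many (at most 0) and the count decides nothing. For the difference between subsets, 8 of 100 drawn splits called as many as the real 124, up to 667, so chance was not excluded by these, which break the pairs of CD8+ and CD8- arrays. Of the 7 others, 4 turn the genotype labels in 1 subset, which brings the common genotype effect into the difference. With that effect removed, 1 of 100 splits called as many, the real one, and the highest other called 1. Of the 35 splits that keep the pairs, 1 called as many, the real one (124 against at most 0, and 211 against 1 with a replicate block within genotype).

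The Mst1/2-KO effect differed between CD8+ and CD8- DCs, by the test of the difference, in 124 genes. Among the named ones the difference was -3.19 for Cox6a2, -2.54 for Alox5, -2.39 for Dab2, -2.18 for Ccl22, -2.15 for Tnip3, -1.16 for Tcf4, -1.13 for Bcl2l11, -0.68 for Cd24a, 1.09 for Esam, 1.43 for Tlr5, 1.55 for Sucnr1, 1.57 for Cr2, 1.57 for Gpm6b, 1.68 for Mid2 and 2.62 for Bmp2. Bmp2, Sucnr1, Cr2, Gpm6b and Mid2 stood at 2.97 to 4.30 in WT CD8+ DCs, near or below the medians of the tested genes per array (4.31 or above). The constant per probe set makes this only a rough guide to background. If these genes lie near it, they had little room to fall there. Their differences therefore do not show an effect limited to CD8- DCs. The call of Mid2 ended without any array other than replicate 1 of WT CD8+, replicates 1 and 3 of WT CD8- or replicate 1 of Mst1/2-KO CD8- DCs (adjusted p up to 0.0773). That of Cd24a ended without any array other than replicate 2 of WT CD8+, replicates 1 and 4 of WT CD8- or replicate 2 of Mst1/2-KO CD8- DCs (adjusted p up to 0.0753). The median differences of the lists were -0.54 for CD8+ DC identity, -0.55 for plasmacytoid DC markers, -0.47 for cholesterol biosynthesis, -0.16 for BCL2 family and apoptosis and 0.21 for immediate-early and heat-shock genes.

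In groups of 4 arrays, 1 array stood far from the other 3 for 16 of 304 gene groups and 7 of 174 list groups, and chance gives about 1 in 20. The gap to the nearest array over the range of the group was 0.841 for Sema7a (replicate 4 at 6.98, others 7.65 to 7.78), 0.87 for Esam (replicate 1 at 5.15, others 4.63 to 4.70), 0.969 for Mcm2 (replicate 4 at 7.80, others 7.42 to 7.43), 0.897 for Ms4a1 (replicate 2 at 5.00, others 4.54 to 4.58) and 0.912 for Cd274 (replicate 4 at 8.61, others 9.12 to 9.16) in Mst1/2-KO CD8- DCs. In WT CD8- DCs it was 0.91 for Gpm6b (replicate 1 at 6.86, others 7.44 to 7.50), 0.866 for Bst2 (replicate 2 at 8.75, others 9.22 to 9.29), 0.955 for Oas2 (replicate 1 at 7.86, others 8.99 to 9.05), 0.887 for Il7r (replicate 1 at 7.77, others 8.70 to 8.82) and 0.885 for the proliferation list (replicate 3). In Mst1/2-KO CD8+ DCs it was 0.952 for Cd63 (replicate 4 at 6.02, others 7.05 to 7.10), 0.943 for Tnip3 (replicate 1), 0.841 for Sucnr1 (replicate 2) and 0.886 for the BCL2 family and apoptosis list (replicate 4). In WT CD8+ DCs it was 0.892 for Psca (replicate 1 at 6.62, others 7.43 to 7.53), 0.87 for Bcl2l11 (replicate 1), 0.832 for Alox5 (replicate 4) and 0.943 for Bex6 (replicate 2 at 5.47, others 4.41 to 4.47). In WT total DCs it was 0.944 for NK cell markers (replicate 1 at 5.81, others 5.36 to 5.39), 0.896 for neutrophil markers (replicate 4), 0.933 for MHC class II presentation (replicate 1), 0.954 for immediate-early genes (replicate 3 at 9.93, others 9.54 to 9.56) and 0.879 for lysosome (replicate 3).

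Probe sets outside the gene tests gave calls as well. Those shared by several genes gave 23 in CD8+ DCs, 51 in CD8- DCs, 307 between the WT subsets, 5 after anti-CD40 and 156 for Rag1-KO against WT. Those without a gene name gave 6 in CD8+ DCs, 32 in CD8- DCs, 5 for the difference of the effects, 667 between the WT subsets, 8 after anti-CD40 and 33 for Rag1-KO against WT.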

How the results depend on the processing

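The settings that leave out arrays by their T cell, NK cell or interferon-stimulated genes were chosen after seeing the data. Of 1801 pairs of a named gene and a setting, leaving out single arrays apart, 1724 kept their direction and side of the threshold, 57 lost the call, 20 gained one and 0 reversed; of 1683 pairs with 1 array left out, 1512 kept both, 168 lost the call, 3 gained one and 0 reversed. Counts of called genes moved by more than 1.5 times in these settings, and the cause was not tested. In CD8+ DCs (197) it was 123 with only the 2 groups. For the difference of the effects (124) it was 222 with array weights and 211 with a replicate block within genotype. In total DCs (188) it was 296 with genes above the median gene only, 340 with an intensity trend and robust eBayes, 764 with all 34 arrays and 108 with a replicate block. In experiment 1 (0) it was 209 with all 34 arrays and 85 without the Rag1-KO arrays lowest in interferon-stimulated genes. For anti-CD40 (8) it was 1 with genes above the median gene only, 17 with the trend, 4 with array weights, 62 with all 34 arrays and 0 with a replicate block, and for Rag1-KO against WT (81) it was 4 with genes above the median gene only, 44 with array weights and 2 with a replicate block. Without the arrays highest in T or NK cell markers the counts were 169 (total DCs), 1126 (CD8- DCs) and 4119 (WT subsets).

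With 1 array left out, the counts ranged from 114 to 209 in CD8+ DCs, 918 to 1533 in CD8- DCs, 79 to 259 for the difference, 4033 to 4545 for the WT subsets, 39 to 169 in total DCs, 0 to 0 in experiment 1, 39 to 136 for anti-CD40 and 195 to 234 for Rag1-KO against WT, and list counts from 9 to 10, 14 to 18, 4 to 9, 18 to 21, 11 to 16 and 9 to 14 for the first 6 of these. With an estimated correlation camera called 1 of 17 lists in CD8- DCs, 2 of 5 for the difference, 5 between the WT subsets (21), 1 of 16 in total DCs and 0 of 11 in experiment 1. With fry the counts were 3 for the difference, 5 in total DCs and 0 in experiment 1, with the mean of all probe sets 8 for the difference, and with genes above the median gene only 13 between the WT subsets. Changes in genes with signal near background are compressed on arrays, which limits the folds of dim genes.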

Other observations

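The test of a direction shared with the p38 label was chosen before its result was seen. Of the 36 genes other than Stk4 that were called in all 3 Mst1/2-KO comparisons, 30 moved the same way in the arrays labelled Rag1-KO p38-KO, among them Plcb4 (1.86), Ccr7 (-1.12), Socs2 (-1.85), Fscn1 (-1.31), Cd274 (-1.16) and Anxa3 (-1.53), the genes being chosen after their values were seen. A state shared by Mst1/2-KO DCs and the arrays labelled Rag1-KO p38-KO may be a candidate explanation, but 6 of the 35 splits of the experiment 1 arrays gave as many genes (up to 35), so chance is not excluded. These splits do not keep the arrays of 1 replicate number together as pairs, although such arrays share deviations in experiment 1. The test asks whether the real split stands out and does not exclude a shared state. Rag1-KO replicates 3 and 4 of experiment 1 stood apart from replicates 1 and 2 in these data.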
